A study of Mus musculus with 16 samples.

How the data were processed

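RNA of quadriceps muscle from 16 mice was hybridised to Affymetrix mouse arrays, 1 mouse per array and 4 mice in each of 4 groups: control and Mfn2 KO at 6 and at 22 months of age. Per the labels, 25 ng of total RNA was amplified with a whole transcriptome kit, biotin labelled, and processed with RMA and the affy package, whose versions are not given. The deposited values are log2 signals per probe set, made by the authors with RMA, which includes background correction, quantile normalization and median polish. All 16 columns of the value table were used.

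The table held 45037 probe sets besides 104 control probe sets, which were left out of all tests. By the probe table supplied with the data, 28898 probe sets carried 1 gene symbol, 551 carried several and 15588 carried none. Of the first kind 28689 had their gene ID in the RefSeq table of assembly GRCm38.p6, and 0 of these had another symbol there. A gene was represented by the probe set with the highest mean over all arrays among those with 1 symbol, which gave 17097 genes, of which 7180 had more than 1 probe set. No gene was filtered on its level. Xist and the Y-linked Eif2s3y, Kdm5d and Uty were read as a check of labels and were not tested. Eif2s3y lay between 7.01 and 8.05 in all arrays. Xist lay between 3.53 and 4.12 in the 8 arrays of numbers 1 and 2 and between 5.47 and 6.26 in the 8 of numbers 3 and 4, so that it followed the replicate number and not the group. Uty went the other way, from 4.89 to 5.32 in numbers 1 and 2 and from 4.27 to 4.82 in numbers 3 and 4. For Eif2s3y and Kdm5d the ranges of these arrays overlapped.

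Groups were compared with limma 3.58.1 in R 4.3.3, fitting all 16 arrays with 1 mean per group, empirical Bayes moderation with a trend on the mean level, two-sided tests and Benjamini-Hochberg adjustment over all genes (adjusted p under 0.05). The comparisons were genotype at each age, age in each genotype, their interaction, and genotype and age averaged over the other factor. Mfn2 probe sets were also compared with an exact two-sided permutation test over all 70 splits of 4 against 4 mice. Figures were drawn with matplotlib 3.10.9.

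The pairing of arrays by replicate number was checked. After removal of group means, arrays of different groups with the same number correlated between 0.289 and 0.780 (24 pairs, median 0.677), against a median of -0.455 for different numbers, and 9 of 16 arrays correlated best with an array of their own number, since numbers 1 and 2 resembled each other. The replicate number was therefore also fitted as a fixed block. This left the fold changes as they were and lowered the median SE of a comparison of 2 groups from 0.157 to 0.0923. What the number stands for is not stated in the labels. Family, which the labels also give, was not balanced: A and B held old mice alone and C and D young mice alone.

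Of 46 gene lists written from general knowledge of muscle, mitochondria, ageing and other cell types, 45 with at least 5 measured members were tested with camera (preset correlation 0.01, Benjamini-Hochberg over lists within a comparison), and the other, of sex-linked genes, served as the check of labels. Lists could share members, such as Cd36 in the slow fibre and fatty acid oxidation lists and Pfkm, Eno3 and Pgam2 in the fast fibre and glycolysis lists. A camera call states that the members rank above or below the other genes. It was repeated with a correlation estimated for each list, and with fry. Counts of lists past the threshold were 23 for genotype in young mice, 17 for genotype in old mice, 18 for age in control mice, 31 for age in KO mice, 19 for the interaction, 19 for genotype and 25 for age over all mice. With an estimated correlation they were 0, 1, 0, 0, 0, 0 and 2 in that order, and with directional fry 0 in each. The groups, comparisons, lists, tests, the rule for named genes and most alternatives were chosen before the data were examined. Alternatives combining the replicate block with another choice, or with the pyruvate carboxylase signal in the fit, were chosen after seeing the data.

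The rule for named genes admitted, in each comparison, Mfn2, the 8 genes with the largest rise and the 8 with the largest fall among those called, up to 4 members with the smallest p in the direction of each list that passed, up to 3 of each cell type list that passed, and, where under 5 genes were called, the 10 genes with the smallest p. The genes and lists described are a selection from those admitted, made after their values were seen.

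The resemblance of the young KO to ageing was measured as Pearson r across genes. Values with no effect came from 100 draws of residual arrays with group labels shuffled within replicate number. The procedure was tested on simulated data with 200 genes changed. The noise was normal and independent between genes, with the residual SD of each gene and its replicate number differences. For genotype in young mice without the block 12 of 67 genes changed by 0.5, 52 of 67 changed by 1 and 65 of 66 changed by 2 on the log2 scale were recovered with 0 false calls, and with the block 58, 67 and 66 with 10 false calls. For age over both genotypes these were 38, 58 and 66 with 0 false calls, and with the block 63, 67 and 66 with 13 false calls. A list of 20 genes raised by 0.3 was called in both, and 0 of 50 other random lists were called. As the simulated noise was independent between genes, this does not measure false calls for lists whose members vary together.

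Alternatives were the mean of all probe sets, leaving out the lowest 25% or 50% of genes by mean level, quantile normalization or median centring, family as a fixed or random block, the replicate block, eBayes without trend or with trend and robust, array weights, a fold change of at least 1.5, adjusted p under 0.1, probe sets in place of genes, only the groups compared, other list tests, and leaving out each array in turn.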

Results

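Transcript levels were measured in the quadriceps muscle of 16 mice, with 1 array per mouse. The mice formed 4 groups of 4: control and Mfn2 knockout (KO) mice aged 6 months (young) and 22 months (old). Mfn2 encodes mitofusin 2, a protein of the outer mitochondrial membrane that fuses mitochondria. Array medians lay between 4.58 and 4.65 on the log2 scale. The standard deviation (SD) of the values within an array followed the replicate number of the labels, with means of 1.90, 1.93, 1.72 and 1.80 for numbers 1, 2, 3 and 4. Every comparison was therefore also fitted with the replicate number as a block, named the replicate block here. The number of arrays limits the precision.

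**Figure D1:**
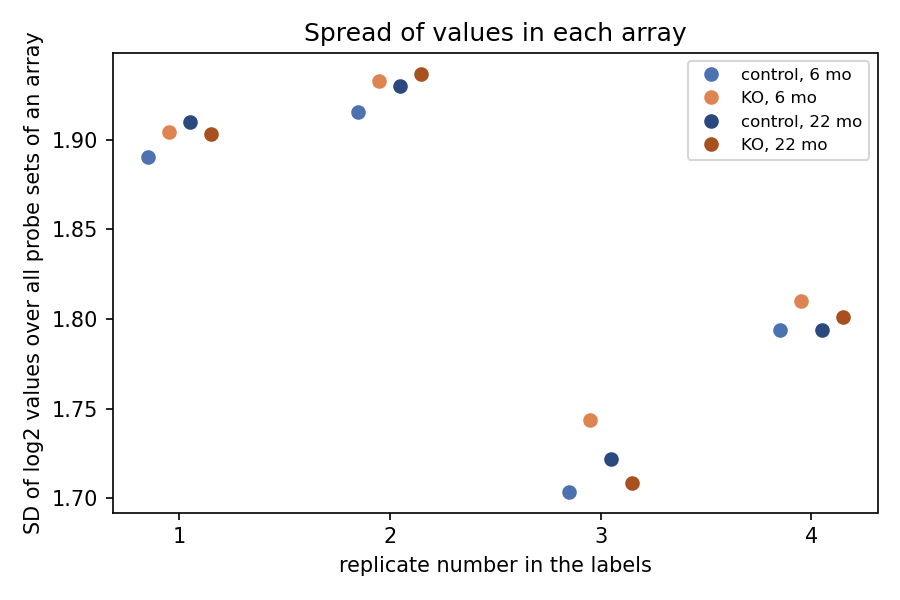
SD of the log2 values over all probe sets of each array (vertical axis, log2 units) against the replicate number in the labels (horizontal axis), with 1 point per array coloured by group. The lowest array lay at 1.70 and the highest at 1.94, and the 4 arrays of one number lay together whatever their group.

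The first comparison asked whether the Mfn2 transcript was lower in KO muscle and in old muscle. In old mice Mfn2 (probe set 1448131_PM_at) averaged 8.68 ± 0.36 in control and 7.74 ± 0.96 in KO muscle (log2, SD, n = 4 each), which is 1.91-fold lower in KO, with a lower value in 4 of 4 replicate numbers. In young mice it averaged 8.80 ± 0.60 in control and 8.45 ± 0.07 in KO muscle (log2, SD, n = 4 each), or 78.8% of the control level. Between 6 and 22 months Mfn2 differed by -0.12 in control muscle (standard error, SE, 0.38) and by -0.71 in KO muscle (SE 0.38), and with the replicate block the SE was 0.24. In KO muscle it was lower in old mice in 4 of 4 numbers, and an exact permutation within the numbers gave p = 0.125 for age in KO mice and for genotype in old mice, the smallest that 4 pairs can give. The exact two-sided permutation p was 0.0286 for genotype in old mice and 0.0286 for age in KO mice, the smallest that 4 against 4 mice can give, and 0.0571 for both after Benjamini-Hochberg adjustment over the 4 comparisons. The exact permutation p was 0.314 for genotype in young mice and 0.771 for age in control mice, or 0.375 and 0.5 within the numbers. Neither Mfn2 difference passed, and 4 mice per group cannot exclude one. In both comparisons Mfn2 was higher in 1 of 4 numbers. Young control replicate 3 was the lowest of its group at 8.03. With the block and without number 3 arrays, a setting chosen after seeing the data, the young KO difference was -0.57 (limma unadjusted p = 0.00237). Mfn2 in old KO replicate 3 stood at 6.32, and without that array the difference was -0.46 for genotype in old mice and -0.24 for age in KO mice. The other Mfn2 probe set (1451900_PM_at) was dim, with group means of 4.22 to 4.42, and differed by 0.13 between old KO and old control muscle, opposite in sign to the brighter one. Whether either probe set lies within the deleted part of the gene was not analysed here.

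**Figure D2:**
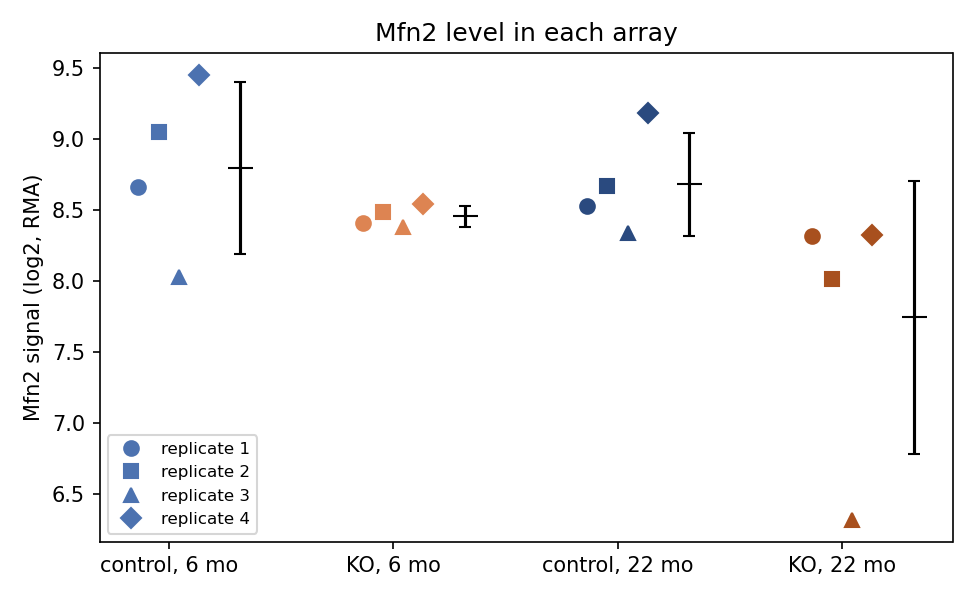
Mfn2 signal of probe set 1448131_PM_at (vertical axis, log2 RMA value) in each of the 16 arrays, by group (horizontal axis); marker shapes give the replicate number, and black bars give the mean and SD (n = 4). Old KO replicate 3 stood at 6.32, and the other old KO arrays lay between 8.01 and 8.32.

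Ageing was compared over both genotypes, 8 old against 8 young mice, to describe which transcripts differ between 6 and 22 months. Matrix genes fell with age: Col1a1 by 1.04 (SE 0.17, adjusted p = 0.0290) and Col3a1 by 0.81 (SE 0.10, adjusted p = 0.00275), the main fibrillar collagens, and Sparc, a collagen-binding matrix protein, by 0.35 (SE 0.05, adjusted p = 0.00534) on the log2 scale. Mlf1 fell by 0.76 (SE 0.08, adjusted p = 0.000841), Nrep by 0.83 (SE 0.11, adjusted p = 0.00797) and Smad3, a transducer of TGF-beta signals, by 0.42 (SE 0.07, adjusted p = 0.0495). The immunoglobulin kappa joining segment Igkj1 rose 8.71-fold (log2 3.12, SE 0.47, adjusted p = 0.0156), Dkk3, a secreted protein of the Dickkopf family, 4.91-fold (SE 0.36 on the log2 scale, adjusted p = 0.0209), and Amy1, an amylase, 2.14-fold (log2 1.10, SE 0.16, adjusted p = 0.0124). Pdlim3, a protein of the muscle Z-disc, rose by 0.24 (SE 0.036, adjusted p = 0.0156). These were the 4 genes that rose and the 6 that fell of 17097 tested, and each of the 10 had the same sign in 4 of 4 replicate numbers. With the replicate block 54 genes rose and 45 fell, the 10 above among them. All 99 had the same sign in control and KO muscle, and their median absolute change was 0.49 on the log2 scale. Calling genes on the mean age difference of these same arrays favours equal signs, across genotypes and replicate numbers. Of the 99 genes, 8 had an unadjusted interaction p under 0.05 in limma with the block. Genes called with the block that rose included the chemokine Ccl8 (log2 1.66, SE 0.29), the complement component C4b (1.27, SE 0.23), the stress-responsive repeat protein Ankrd1 (1.32, SE 0.24), and the p53 targets Eda2r (0.99, SE 0.13) and Sesn1 (0.72, SE 0.10). Those that fell included Col5a2 by 0.82 (SE 0.11), Col5a1 by 0.70 (SE 0.09) and the transferrin receptor Tfrc by 0.76 (SE 0.14) on the log2 scale.

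**Figure D3:**
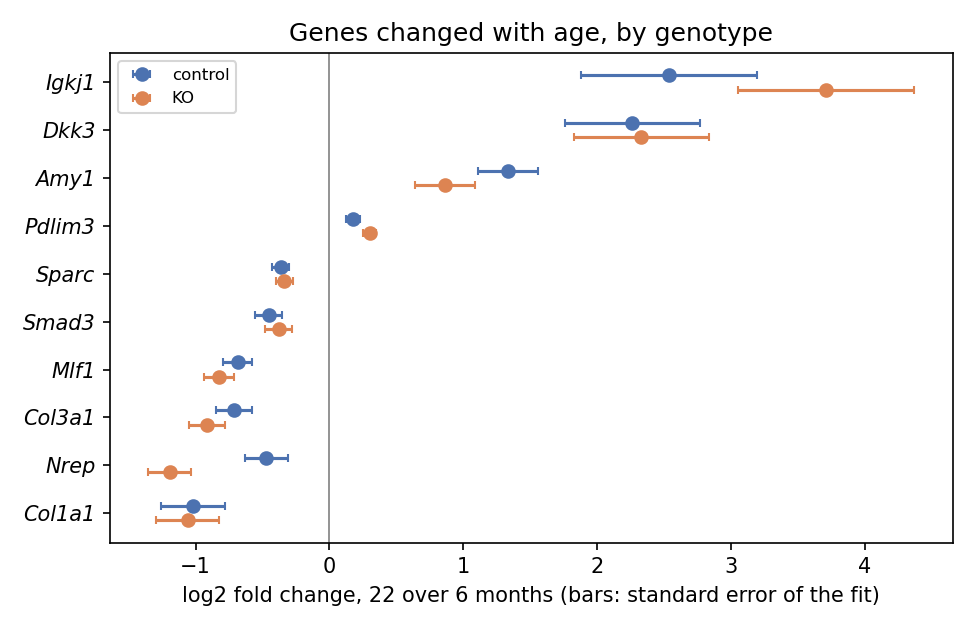
Log2 fold change between 6 and 22 months (horizontal axis) of the 10 genes that changed with age over both genotypes (vertical axis), in control and in KO muscle; points are estimates and bars their SE (n = 4 mice per group). Each gene had the same sign in control and KO muscle, which calling genes on the mean of both differences favours, from Igkj1 at the top to Col1a1 at the bottom.

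Of 36 collagen and extracellular matrix genes, 30 were lower in old muscle (median log2 -0.23). Among them 3 fell over all genes tested and 8 adjusted over the list alone, and with the replicate block 7 and 19. The list ranked below other genes (camera adjusted p = 3.72e-17; adjusted p = 0.145 with an estimated correlation). Macrophage markers ranked above other genes, with 15 of 16 members higher in old muscle (median 0.30, camera adjusted p = 3.76e-14; adjusted p = 0.0424 with an estimated correlation, or 0.128 with the block as well). Of these markers 0 rose over all genes tested with limma and 2 adjusted over the list alone, and 1 (Mpeg1, log2 0.45, SE 0.09) and 9 with the block. Inflammatory cytokines and NF-kB targets were higher in 25 of 31 members (median 0.05, camera adjusted p = 4.38e-05; adjusted p = 0.0424 with an estimated correlation, or 0.0908 with the block as well), where 3 rose adjusted over the list alone and 1, Ccl8, over all genes with the block. Antigen presentation genes were higher in 14 of 16 members (median 0.31, camera adjusted p = 2.52e-13; adjusted p = 0.108 with an estimated correlation), with 4 that rose adjusted over the list alone, 11 with the block, and 0 over all genes in either limma fit. Complement genes were higher in 12 of 13 members (median 0.24, camera adjusted p = 2.75e-11; adjusted p = 0.136 with an estimated correlation), with 5 that rose adjusted over the list alone and 1, C4b, over all genes with the block. Granulocyte and mast cell markers were higher in 10 of 12 members (median 0.08, camera adjusted p = 3.78e-06; adjusted p = 0.108 with an estimated correlation), with 3 that rose adjusted over the list alone. The mast cell proteases Mcpt4 (log2 0.55, SE 0.11) and Cma1 (0.45, SE 0.09) rose over all genes with the block. With family and the block in the fit, macrophage markers (median -0.0578, camera adjusted p = 0.335), complement (-0.0720, 0.849), antigen presentation (-0.0015, 0.994) and granulocyte and mast cell markers (0.058, 0.0933) lost their calls. The collagen and cytokine lists kept theirs. With the pyruvate carboxylase signal described below and without the block, the collagen median was -0.11 (camera adjusted p = 0.000289).

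Muscle atrophy genes and ubiquitin ligases were higher with age in 20 of 22 members (median 0.12, camera adjusted p = 1.14e-10; adjusted p = 0.145 with an estimated correlation), with 1 that rose adjusted over the list alone, 4 with the block, and 0 over all genes in either limma fit. Senescence and p53 targets were higher in 13 of 17 members (median 0.05, camera adjusted p = 0.00347; adjusted p = 0.156 with an estimated correlation), with 2 that rose adjusted over the list alone and 2, Eda2r and Sesn1, over all genes with the block. Autophagy genes were higher in 24 of 30 members (median 0.05, camera adjusted p = 0.00477; adjusted p = 0.634 with an estimated correlation), with 1 that rose adjusted over the list alone and 1 over all genes with the block. That gene was Gabarapl1 (log2 0.36, SE 0.06), a protein of the autophagosome membrane. Mitophagy receptors were higher in 8 of 10 members (median 0.08, camera adjusted p = 0.0145; adjusted p = 0.546 with an estimated correlation), with 0 that rose adjusted over the list alone, 4 with the block, and 0 over all genes in either limma fit. Without the block 0 members of these lists other than the collagen list passed over all genes. Limma gave 601 genes at unadjusted p under 0.05 for age, and 1996 with the replicate block. The labels place families A and B among old mice alone and C and D among young mice alone, and with family in the fit 0 genes passed. The age difference then rests on the mice labelled Other. Differences between families and a loss of precision cannot be told apart there. The 3 prime minus 5 prime signal of the pyruvate carboxylase control was higher in the old array in 8 of 8 pairs of one number and genotype (mean 0.12, two-sided exact permutation p = 0.00781, or 0.0391 adjusted over 5 such controls, of which the other 4 did not pass). Such a signal can follow the state of the RNA, but whether this control measured it here was not tested. The pyruvate carboxylase signal also separated numbers 1 and 2 (mean -0.236) from numbers 3 and 4 (mean 0.110) with no overlap. Without the block its fit therefore cannot tell this signal from the replicate number. With this signal and without the block 283 genes rose and 155 fell, and with both in the fit 0 of the 99 genes were called. All 99 kept their sign, their change was a median 0.935 of that without it, and the median SE went from 0.0893 to 0.145. Autophagy (median 0.030, camera adjusted p = 0.338), mitophagy (0.074, 0.137) and senescence genes (0.057, 0.341) lost their calls with the signal and the block. Autophagy (0.026, 0.303) and mitophagy genes (0.055, 0.366) also lost theirs with family and the block. With the signal and without the block, autophagy (median 0.13, camera adjusted p = 1.58e-05), mitophagy and senescence genes kept their calls. In that fit cytokine genes (0.037, 0.0797) and granulocyte and mast cell markers (0.0082, 0.276) lost theirs. Of 16 runs that left out 1 array the autophagy list kept its call in 11 and the mitophagy list in 12, and both in 16 of 16 with the block. The mitophagy median turned to -0.0234 without young control replicate 3 and to -0.0061 without young KO replicate 3. It was 0.0015 without old control replicate 2 and 0.0073 without old KO replicate 2. The senescence list kept its call, but its median was 0.021 without young KO replicate 2 and 0.13 without old KO replicate 3. With the block it was 0.016 without old control replicate 3. Without young KO replicate 1 the count fell from 10 to 5, and of 16 runs that left out 1 array Smad3 kept its call in 3, Col1a1 in 5, Dkk3 in 8, Pdlim3 in 14 and Igkj1 in 15, against 16 of 16 with the block.

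Age in control mice alone addressed what old muscle of the control genotype looks like. With the replicate block, whose SEs are given here, 7 genes rose and 1 fell. Amy1 rose 2.52-fold (log2 1.33, SE 0.18, adjusted p = 0.0352), Spock2 2.71-fold (log2 1.44, SE 0.23, adjusted p = 0.0466) and Ak4, a mitochondrial adenylate kinase, 2.59-fold (log2 1.37, SE 0.22, adjusted p = 0.0466). Map7 (0.66, SE 0.10), the phosphatase Dusp26 (0.63, SE 0.10), Rhpn2 (0.45, SE 0.06) and the small heat shock protein Cryab (0.35, SE 0.05) rose as well, and Mlf1 fell by 0.69 (SE 0.11) on the log2 scale. Dimmer probe sets of Ak4 and Cryab had the opposite sign (-0.20 for Ak4 and -0.02 for Cryab). Macrophage markers were higher in old control muscle in 15 of 16 members (median 0.37, camera adjusted p = 7.28e-12; adjusted p = 0.134 with an estimated correlation). Among them were Adgre1 (0.89, SE 0.20) and Cd14 (0.32, SE 0.06), and 1 rose adjusted over the list alone and 8 with the block. Complement genes were higher in 13 of 13 members (median 0.36, camera adjusted p = 1.18e-09; adjusted p = 0.416 with an estimated correlation), with 1 that rose adjusted over the list alone and 6 with the block. Fatty acid oxidation genes were higher in 23 of 23 members (median 0.25, camera adjusted p = 8.56e-12; adjusted p = 0.416 with an estimated correlation), with 1 that rose adjusted over the list alone. Mitophagy receptors were higher in 7 of 10 members, among them Bnip3 (0.20, SE 0.07) and Pink1 (0.18, SE 0.05), with 0 that rose adjusted over the list alone and 2 with the block (median 0.19, camera adjusted p = 0.00356; adjusted p = 0.505 with an estimated correlation). Collagen and matrix genes were lower in 31 of 36 members (median -0.18, camera adjusted p = 3.49e-10; adjusted p = 0.416 with an estimated correlation), with 5 that fell adjusted over the list alone and 10 with the block. Over all genes, 0 members of these 5 lists passed in either limma fit. With family and the block in the fit, macrophage markers (median -0.0494, camera adjusted p = 0.756), complement (0.071, 0.650), fatty acid oxidation (0.082, 0.227) and mitophagy receptors (0.19, 0.0557) lost their calls. Without the block limma called 0 genes at this threshold and 363 at unadjusted p under 0.05, and 1648 with it. The 8 genes called with the block became 1 with family, 2 without number 3 arrays and 3 for the mean of probe sets. Without young control replicate 3 the median of fatty acid oxidation genes was 0.041 and that of mitophagy receptors -0.0053. The latter lost their call there and without old control replicate 2 (0.096, camera adjusted p = 0.0623). The collagen list kept its call without each single array. Its median was -0.0739 without young control replicate 2 and -0.0904 without old control replicate 3. It was -0.31 without young control replicate 3, -0.29 without young control replicate 4 and -0.29 without old control replicate 2. With the pyruvate carboxylase signal it was -0.0791 (camera adjusted p = 0.00117). Leaving out single arrays moved the blocked count between 0 (without young control replicate 1 or 2, young KO replicate 2, old control replicate 1 or old KO replicate 2) and 15 (without young KO replicate 4).

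Age in KO mice addressed whether KO muscle ages alike. Mlf1 fell by 0.82 (SE 0.11, adjusted p = 0.0135), Nrep by 1.19 (SE 0.16, adjusted p = 0.0135) and Col3a1 by 0.92 (SE 0.14, adjusted p = 0.0313) on the log2 scale between 6 and 22 months. These were the 3 genes called, and with the replicate block Eda2r rose as well, 2.62-fold (log2 1.39, SE 0.19, adjusted p = 0.0160). Antigen presentation genes were higher in old KO muscle in 16 of 16 members (median 0.61, camera adjusted p = 1.35e-19; adjusted p = 0.0750 with an estimated correlation). Among them were the class II gene H2-Aa (0.86, SE 0.25), the class I gene H2-D1 (0.55, SE 0.18) and the immunoproteasome subunit Psmb9 (0.66, SE 0.20), and 9 rose adjusted over the list alone. Interferon response genes were higher in 25 of 28 members (median 0.28, camera adjusted p = 5.64e-14; adjusted p = 0.142 with an estimated correlation), with 3 that rose adjusted over the list alone and 6 with the block. Muscle atrophy genes were higher in 20 of 22 members (median 0.14, camera adjusted p = 7.36e-10; adjusted p = 0.142 with an estimated correlation), with 0 that rose adjusted over the list alone in either fit; the ubiquitin ligase Trim63 differed by 0.51 (SE 0.24). Complex I genes were lower in 32 of 33 members (median -0.09, camera adjusted p = 4.41e-16; adjusted p = 0.179 with an estimated correlation), among them Ndufs6 (-0.18, SE 0.05) and Ndufa9 (-0.15, SE 0.05), and mitochondrial ribosome genes in 37 of 40 (median -0.12, camera adjusted p = 8.71e-07; adjusted p = 0.518 with an estimated correlation). Adjusted over the list alone 0 genes of either list fell. Collagen and matrix genes were lower in 27 of 36 members, with 1 that fell over all genes and 10 adjusted over the list alone (median -0.26, camera adjusted p = 1.66e-13; adjusted p = 0.194 with an estimated correlation). Over all genes 0 members of the other 5 lists passed in either limma fit, and 443 genes had an unadjusted p under 0.05 in KO mice, or 1751 with the block. With family and the block in the fit, antigen presentation (median 0.13, camera adjusted p = 0.299) and interferon response (0.15, 0.0511) lost their calls. Without old KO replicate 1 the interferon response median was 0.081. The muscle atrophy list kept its call, with a median of 0.22 without young KO replicate 1 or 2 and 0.090 without young KO replicate 3. Without old KO replicate 3 mitochondrial ribosome genes lost their call (-0.021, 0.192), as they did with the pyruvate carboxylase signal in the fit (-0.019, 0.640). With this signal the collagen median was -0.0798 (0.000898), or -0.16 with the block as well (0.000225). The 3 genes became 0 with family, 0 when only the 2 groups were fitted, 0 with the block and this signal and 1 with family and the block. Without young KO replicate 2, 3 or 4 the count of genes was 0, and without young KO replicate 1 it was 1.

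**Figure D4:**
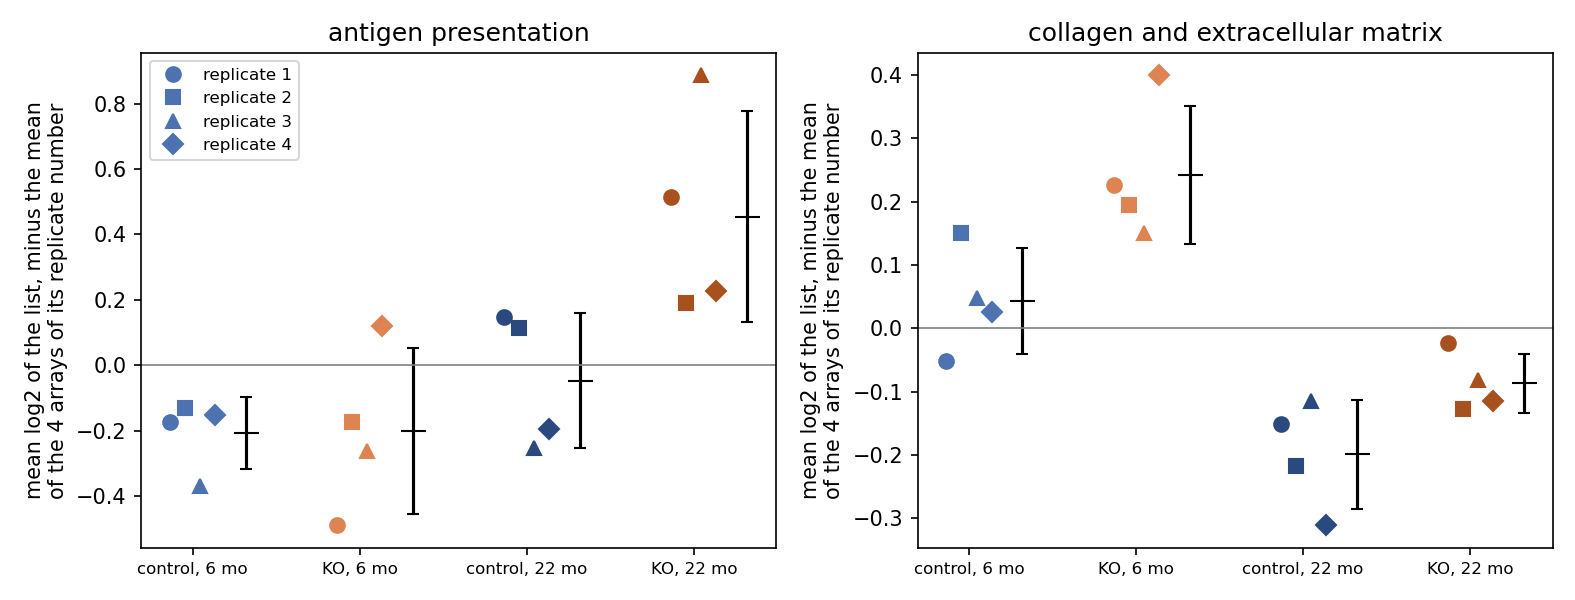
Mean log2 signal of the antigen presentation genes (left) and of the collagen and extracellular matrix genes (right) in each array, less the mean of the 4 arrays of its replicate number (vertical axes, log2), by group (horizontal axes); marker shapes give the replicate number and black bars the mean and SD (n = 4). The 4 old KO arrays were the highest of their numbers for antigen presentation, and the 4 old KO and 4 old control arrays lay below 0 for collagen.

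Genotype in young mice addressed how KO muscle differs before old age. Adipocyte markers were lower in young KO muscle in 14 of 17 members (median -0.35, camera adjusted p = 9.90e-12; adjusted p = 0.292 with an estimated correlation). The fat cell hormones Adipoq (-2.93, SE 0.81) and Retn (-1.25, SE 0.35) and the lipogenic gene Thrsp (-1.05, SE 0.29) were among them, and 4 fell adjusted over the list alone. Slow fibre genes were higher in 17 of 17 members (median 1.07, camera adjusted p = 2.63e-09; adjusted p = 0.473 with an estimated correlation), such as Myoz2 (1.28, SE 0.78), which binds calcineurin at the Z-disc. This list also held Myh2, a myosin of fast oxidative fibres. Fast fibre genes were lower in 16 of 19 members (median -0.09, camera adjusted p = 6.05e-06; adjusted p = 0.460 with an estimated correlation), such as the fast troponin I gene Tnni2 (-0.11, SE 0.03) and Actn3 (-0.15, SE 0.07), and adjusted over the list alone 0 fell, or 6 with the block, where 1 rose. Fatty acid oxidation genes were higher in 21 of 23 members (median 0.24, camera adjusted p = 9.74e-13; adjusted p = 0.473 with an estimated correlation), such as Acadm (0.39, SE 0.16) and Pdk4 (0.63, SE 0.25), a kinase that restrains glucose oxidation. The median of this list was above 0 in 2 of 4 replicate numbers. Collagen and matrix genes were higher in 33 of 36 members (median 0.21, camera adjusted p = 1.95e-07; adjusted p = 0.511 with an estimated correlation), such as Col6a3 (0.64, SE 0.32). Endothelial and pericyte markers were higher in 17 of 18 members (median 0.19, camera adjusted p = 1.27e-05; adjusted p = 0.599 with an estimated correlation), such as the pericyte gene Rgs5 (0.36, SE 0.10), with 1 that rose adjusted over the list alone and 2 with the block. Without young control replicate 3 the slow fibre median was 0.45, or 0.38 with the block, where the call was lost (camera adjusted p = 0.133). The fatty acid oxidation median was then 0.086 and that of endothelial and pericyte markers 0.064 (0.0428). The collagen, adipocyte and fast fibre lists kept their calls without each array, but their medians moved. For collagen it was 0.13 without young KO replicate 2, 0.34 without young KO 3 and, with the block, 0.11 without young KO 4. For adipocyte markers it was -0.22 without young control replicate 2 and, with the block, -0.19 without young control 4. For fast fibre genes it was -0.045 without young KO replicate 2. In the slow fibre, fatty acid oxidation and collagen lists 0 genes passed adjusted over the list alone. Limma called 0 genes over all genes with or without the block, and 291 genes had an unadjusted p under 0.05, or 1612 with the block. The genes with the smallest p included Wdr61 (0.96, SE 0.15 with the block), Fnip1 (0.99, SE 0.18), which binds folliculin, and Marcks (0.74, SE 0.14), none of which passed.

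Genotype in old mice asked the same in aged muscle. Antigen presentation genes were higher in old KO muscle in 16 of 16 members (median 0.48, camera adjusted p = 1.05e-16; adjusted p = 0.133 with an estimated correlation). The immunoproteasome subunits Psmb8 (0.99, SE 0.44) and Psmb9 (0.60, SE 0.20) and the class I genes H2-K1 (0.49, SE 0.18) and H2-D1 (0.48, SE 0.18) were among them, and 0 rose adjusted over the list alone, or 7 with the block. A dimmer Psmb9 probe set differed by -0.07. Interferon response genes were higher in 26 of 28 members (median 0.29, camera adjusted p = 5.58e-17; adjusted p = 0.177 with an estimated correlation), such as the interferon-induced GTPases Iigp1 (2.58, SE 0.70), Tgtp1 (1.61, SE 0.50) and Igtp (1.33, SE 0.45), with 0 that rose adjusted over the list alone and 5 with the block. Antioxidant and NRF2 target genes were higher in 17 of 25 members (median 0.07, camera adjusted p = 0.000329; adjusted p = 0.720 with an estimated correlation), with 1 that rose adjusted over the list alone and 5 with the block. Sulfiredoxin (Srxn1, 0.85, SE 0.17) and catalase (Cat, 0.41, SE 0.21) were among the higher members. Glycolysis and glycogen genes were lower in 16 of 20 members and kept their call with an estimated correlation (median -0.08, camera adjusted p = 3.62e-10; adjusted p = 0.0193 with an estimated correlation). With the replicate block that value was 0.122. Phosphofructokinase (Pfkm, -0.09, SE 0.021) and beta-enolase (Eno3, -0.12, SE 0.04) were in that list, and 1 member fell adjusted over the list alone. Limma called 0 genes over all genes with or without the block, and 195 genes had an unadjusted p under 0.05, or 1131 with the block. Without old KO replicate 2, 1 gene passed. Without old KO replicate 3 the antigen presentation median was 0.31 and without old control replicate 4 it was 0.29. Without old KO replicate 1 the interferon response median was 0.093. The antioxidant list lost its call without old control replicate 3 (0.0064, camera adjusted p = 0.146) or old KO replicate 2 (0.0011, 0.0945).

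Over both ages together, 8 KO against 8 control mice, collagen and matrix genes were higher in 33 of 36 members (median 0.14, camera adjusted p = 3.93e-10; adjusted p = 0.388 with an estimated correlation). Fast fibre genes were lower in 18 of 19 members (median -0.06, camera adjusted p = 1.56e-10; adjusted p = 0.103 with an estimated correlation), with 3 that fell adjusted over the list alone, and 8 that fell and 1 that rose with the block. Antioxidant and NRF2 target genes were higher in 16 of 25 members (median 0.04, camera adjusted p = 0.00113; adjusted p = 0.626 with an estimated correlation), with 1 that rose adjusted over the list alone and 5 with the block, and lost their call without old control replicate 3 (median -0.00033, 0.0547). Catalase (Cat) differed by 0.38 (SE 0.06 with the block), the lipogenic gene Thrsp by -0.79 (SE 0.16) and the antiproliferative gene Btg2 by 0.65 (SE 0.16), and none of the 3 passed. Limma called 0 genes for genotype over both ages, and 265 had an unadjusted p under 0.05, or 0 and 1448 with the block.

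The genotype by age interaction tested whether the KO differed from control to another extent in old than in young mice. Antigen presentation genes had a higher KO difference (KO less control) in old mice in 16 of 16 members (median 0.50, camera adjusted p = 3.37e-09; adjusted p = 0.278 with an estimated correlation). Adipocyte markers, lower in young KO muscle, had a higher KO difference in old mice in 14 of 17 members. Of these markers 2 passed adjusted over the list alone, and with the block 6 passed this way and 1 the other way (median 0.34, camera adjusted p = 2.59e-09; adjusted p = 0.278 with an estimated correlation). The median KO difference of these markers in old mice was 0.041. The KO difference of Adipoq was higher by 3.87 (SE 1.14) in old mice. Cytosolic ribosome genes had a higher KO difference in old mice in 29 of 31 members (median 0.08, camera adjusted p = 2.86e-10; adjusted p = 0.278 with an estimated correlation). Genes of the tricarboxylic acid cycle had a lower KO difference in old mice in 16 of 16 members (median -0.17, camera adjusted p = 5.35e-09; adjusted p = 0.364 with an estimated correlation), and complex I genes in 31 of 33 (median -0.07, camera adjusted p = 1.39e-08; adjusted p = 0.618 with an estimated correlation). By replicate number the medians were -0.0043, -0.086, -0.43 and -0.023 for the tricarboxylic acid cycle and 0.034, -0.071, -0.25 and -0.0064 for complex I, so number 3 stood apart in both. With family and the block in the fit, antigen presentation (0.19, camera adjusted p = 0.0762), tricarboxylic acid cycle (-0.10, 0.0762) and complex I genes (-0.00055, 0.977) lost their calls. The other 2 lists kept theirs. In these lists other than the adipocyte markers 0 genes passed adjusted over the list alone. Limma called 0 genes for the interaction, and 194 had an unadjusted p under 0.05, or 0 and 1238 with the block.

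The last comparison asked how far the KO in young mice resembled ageing, which the study's title raises. Across 17097 genes the log2 differences of young KO and of old control muscle, both taken against young control muscle, correlated with Pearson r = 0.482. Both contrasts share the young control arrays, and 100 simulated sets with no effect gave a mean r of 0.482 (central 95% from 0.0934 to 0.727, one-sided permutation p = 0.525). With the young control arrays divided so that no array was shared, r averaged 0.0896 over 6 divisions and ranged from 0.00969 to 0.193 (one-sided permutation p = 0.248). The genotype and age differences over all mice, which share no error by design, correlated with r = 0.133 (one-sided permutation p = 0.248). Of the 99 age genes called with the block, such as Col1a1, Col3a1 and Dkk3, 51 had the sign of their age change in young KO muscle and 57 in old KO muscle. The genotype differences in young and old mice correlated with r = 0.106 (one-sided permutation p = 0.297), and the age differences in control and KO mice with r = 0.287 (one-sided permutation p = 0.0792). Genes are not independent replicates, so these correlations describe the profiles and their spread comes from the simulated sets.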

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

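The tests of the 3 patterns below were chosen after the patterns were seen, and the bounds that would exclude an explanation were revised after a first run. For the fibre, single mouse and family explanations the bound was a call kept and a mean difference of the list over 2 times its SE between mice. Counts over other splits of the arrays were planned.

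The spread of values within an array followed the replicate number: arrays of number 3 had a mean SD of 1.72, against 1.93 for number 2. Higher background on number 3 arrays stays open: their nonspecific control probes differed from those of numbers 1 and 2 by -0.0425, which lies within the SD of the arrays (0.0834), in values that had been background corrected. Separate normalization of the numbers stays open too: the sorted values of any arrays lay up to 0.655 apart, against 0.162 between arrays of one number, though those of numbers 1 and 2 lay at most 0.129 apart. The state of the RNA or its amplification stays open too: the 3 prime minus 5 prime signal of the pyruvate carboxylase control was 0.346 higher in numbers 3 and 4 with no overlap between the 8 and 8 arrays, but that of 18S ribosomal RNA was 0.336 lower, again with no overlap, and the other 3 of 5 controls overlapped. The labels name no group that the number could stand for, and no biological explanation was tested.

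Fatty acid oxidation genes were higher and fast fibre genes lower in young KO muscle, beside slow fibre genes. For fast fibre genes the bound was met: with the slow fibre score and the block in the fit their mean went from -0.067 (SE 0.018) to -0.058 (SE 0.018). The camera adjusted p was then 0.000804, or 0.461 with an estimated correlation, which was 0.378 before. The score thus did not account for most of this difference. Fibre makeup of the sampled pieces stays open, since a score that measures it in part can leave such a difference. The slow fibre median went from 1.07 to 0.066. As the score is the mean of these slow fibre genes, this fall follows from the fit and does not show that the score captures fibre makeup. For fatty acid oxidation fibre makeup stays open, since the mean went from 0.26 (SE 0.15) to 0.12 (SE 0.099; camera adjusted p = 0.00155, or 0.597 with an estimated correlation). An effect of Mfn2 loss on slow fibre genes stays open too, since the slow fibre score differed by 1.03 with an exact permutation p of 0.314, in 4 against 4 mice. For fatty acid oxidation the 2 cannot be told apart, because the score of the young control arrays alone ranged from 6.60 to 9.69.

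Antigen presentation genes were higher in old KO muscle, by a median of 0.48. More immune cells in the tissue stays open: 56 pooled immune cell markers, 0 of them antigen presentation genes, differed by a median of 0.0301, at or below 0 in 2 of 4 replicate numbers, camera adjusted p of the 4 immune cell lists lay between 0.225 and 0.783, and the most abundant markers averaged 8.38 ± 0.56 and 8.66 ± 0.45 (Lyz2), 7.28 ± 0.65 and 7.40 ± 0.10 (Mrc1) and 7.12 ± 0.52 and 7.14 ± 0.31 (Tyrobp) in old control and old KO muscle (log2, SD, n = 4), small differences against the spread between mice. The call was kept without each old KO mouse in the fit with the block (highest adjusted p = 6.60e-07, but 0.178 to 0.631 with an estimated correlation, which gave no call with all mice), but a large part from 1 mouse stays open, as without old KO replicate 3 the mean of the list went from 0.50 (SE 0.19) to 0.31 (SE 0.16), or 1.93 times its SE. The family of the mice, 3 of 4 old KO mice being of family A, stays open, with a mean of 0.33 (SE 0.27; adjusted p = 0.000259, or 0.822 with an estimated correlation) with family and replicate number in the fit. Loss of Mfn2 in old mice stays open as well and was not tested apart from these.

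Other splits of the arrays into groups of the same sizes tested whether chance can be excluded. For genes changed with age over both genotypes it can within the replicate block: 1 of 100 splits, the real one, gave as many as the 99 called (highest other 14). Without the block 3 of 100 gave as many as the 10 called (highest other 6754). For lists, splits that ignore the number gave as many in 2 of 100 for age over both genotypes (25 lists, highest other 26). For age in KO mice they did in 1 of 35 (31 lists, highest other 22), the smallest share possible. Chance is not excluded for either, since these splits break the pairing by number. With the block 5 of 100 gave as many for age over both genotypes (24 lists, highest other 26), and for age in KO mice 8 splits are too few. Chance cannot be excluded for the 3 genes of age in KO mice either (2 of 35, highest other 2474). It cannot be excluded for lists of genotype in young mice (23, 3 of 35, highest other 26), of genotype in old mice (17, 7 of 35, highest other 21), of age in control mice (18, 11 of 35, highest other 24), of the interaction (19, 20 of 100, highest other 25) and of genotype over both ages (19, 22 of 100, highest other 27), nor with the block for the last pair (16, 24 of 100, highest other 25, and 16, 21 of 100, highest other 22). For the interaction the splits shuffled all 4 group labels, so their counts also hold age and genotype differences and cannot decide. Where 0 genes were called, every split gives as many by construction, so that share says nothing about chance and only the highest other count is informative. The splits were 35 of 35 for genotype in young mice (highest other 2249), age in control mice (4834) and genotype in old mice (5523), and 100 of 100 for the interaction (0, or 7 with the block) and for genotype over both ages (7434, or 1 with the block). Within the replicate block 8 splits of 2 groups exist, too few for a share under 0.05. There the real and highest other counts of genes were 0 and 0 for genotype in young mice, 8 and 7 for age in control mice, 0 and 0 for genotype in old mice, and 4 and 0 for age in KO mice, and 8, 1, 8 and 1 splits gave as many. The counts of lists were 18 and 13, 12 and 17, 15 and 19, and 29 and 15 in that order, and the splits with as many were 1, 5, 3 and 1. The splits that call many more genes than the real one point to a structure of the samples, as arrays of the same replicate number resembled each other.

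Among 360 groups of 4 arrays of 90 named genes, 23 (6.39%) held an array far from the other 3, and chance gives about 1 in 20. In old KO replicate 3 these were Mfn2 (6.32), H4c9 (5.78) and Adipoq (5.16), all lowest, and Ankrd1 (7.65), highest. In old KO replicate 1, Sparc (10.6) was lowest and Sesn2 (5.83) and Pgk1 (11.4) highest. In young control replicate 3, Ccl8 (4.81) and Tnni2 (12.3) were highest and Amy1 (7.69), Myh2 (9.96) and Polk (6.08) lowest. In young control replicate 4, Pdlim3 (10.8) and Trim63 (9.01) were lowest. In young KO replicate 4, Rasd2 (5.90), Ndufa9 (11.1) and Btg2 (6.61) were lowest and Pdlim3 (10.96) and Actn3 (11.8) highest. In young KO replicate 3, Col5a1 (7.43) and Sesn1 (5.93) were lowest, and in young KO replicate 2 Igtp (6.02) was highest and Pgk1 (11.3) lowest. These are log2 levels.

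The genotype difference was unlike at the 2 ages by the interaction test for 11 of the named lists, with the median log2 difference (old less young) of 0.34 for adipocyte markers, -0.48 for slow fibre genes, -0.15 for endothelial and pericyte markers, -0.24 for fatty acid oxidation, 0.50 for antigen presentation, 0.23 for interferon response, -0.046 for glycolysis and glycogen, -0.075 for complex I, -0.11 for the mitochondrial ribosome, -0.17 for the tricarboxylic acid cycle and 0.085 for the cytosolic ribosome. With the replicate block the slow fibre list no longer passed, and with an estimated correlation 0 lists passed. With family and the block the adjusted p was 0.0762 for antigen presentation, 0.0762 for the tricarboxylic acid cycle, 0.977 for complex I, 0.714 for the mitochondrial ribosome, 0.174 for fatty acid oxidation, 0.174 for glycolysis and glycogen, 0.173 for endothelial and pericyte markers and 0.748 for slow fibre genes, so 3 lists passed. Endothelial and pericyte markers kept their call in 9 of 16 runs that left out 1 array (lost without young control replicate 3 or 4, young KO 1 or 2, old control 2, or old KO 3 or 4), and in 11 of 16 with the block (lost without young KO 4, old control 3 or 4, or old KO 2 or 4). Their median was -0.021 without young control replicate 3 (camera adjusted p = 0.326), -0.071 with the pyruvate carboxylase signal (0.0561) and -0.087 with it and the block (0.196). The mitochondrial ribosome list lost its call without young control replicate 3 (-0.025, 0.207), old control replicate 2 (-0.020, 0.160) or old KO replicate 3 (0.0092, 0.393), and kept it in 16 of 16 runs with the block. Glycolysis genes kept their call in 16 of 16 runs, in 12 of 16 with the block (lost without young control replicate 1 or 4, young KO 4 or old KO 2), and not with the block and the signal (-0.049, 0.0512). Slow fibre genes passed in 8 of 16 runs (not without young control replicate 1 or 3, young KO 1 or 2, old control 2 or 3, or old KO 2 or 4), or 6 of 16 with the block, and not with the signal (-0.36, 0.106). Without young control replicate 3 the fatty acid oxidation median was -0.0995 (0.0498) and that of the tricarboxylic acid cycle -0.0731. The antigen presentation median was 0.33 without old KO replicate 3 and 0.31 without old control replicate 4, that of complex I -0.0388 without old KO replicate 3, and that of the interferon response 0.060 (0.0111) without old KO replicate 1.

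Probe sets without a gene symbol lie outside the gene comparisons, and of 15588 such probe sets 3 passed for age in KO mice and 9 for age over both genotypes (8 and 42 with the replicate block).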

How the results depend on the processing

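Over 62 other settings, 35 of them planned, single arrays left out included, 0 named genes other than Mfn2 turned their sign, 230 gene values gained and 48 lost a call outside the runs that leave out 1 array, and 1887 kept their side of the threshold. Settings that combine the replicate block with another choice, the list tests with the block, and those with the 3 prime minus 5 prime signal of pyruvate carboxylase, named the RNA signal here, were chosen after seeing the data. This name is a label alone, as whether that 1 control of 5 measured the state of the RNA was not tested. The RNA signal also followed the replicate number, so without the block the 2 cannot be told apart. With the replicate block 48 of the 49 list results named in the text kept their side of the threshold and direction, and slow fibre genes for the interaction lost their call. With family fixed 32 kept both, with family and the block 26, and with the block and the RNA signal 42. Where nothing else is said, the cause was not tested. Nonspecific control probes averaged 3.35 to 3.60 per array, so a gene near that level has little room to fall. Counts are given where they differ from the reported one by more than 1.5 times.

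Genes called for age over both genotypes were 10 and became 22 with the lowest 50% of genes left out, 40 with quantile normalization, 29 with family as a random block, 99 with the replicate block, 80 with array weights, 22 at adjusted p under 0.1, 21 for probe sets and 438 with the RNA signal. With the block and the RNA signal they were 0, as the SE rose. With the block they were 111 for the mean of probe sets, 103 with the lowest 50% left out, 147 with array weights, 102 with arrays scaled to one spread, 138 with the slow fibre score and 38 with number 3 arrays left out, which drops 4 arrays. Family as a fixed block gave 0, or 1 with the block. The age difference then rests on the few mice labelled Other, so differences between families and a loss of precision cannot be told apart. The mice labelled Other shared 1 family term in the fixed block, and each was a family of its own in the random block. For age in control mice the count of 0 became 1 with quantile normalization or the RNA signal, 8 with the block, 10 with array weights, and with the block 3 for the mean of probe sets, 1 with family, 9 with array weights, 9 with scaled arrays, 14 with the slow fibre score and 2 without number 3 arrays. For age in KO mice the count of 3 became 0 with family fixed, 5 with family random, 8 with array weights or the RNA signal, 6 for probe sets and 0 when only the 2 groups were fitted, and with the block 1 with family, 29 with array weights, 5 with scaled arrays, 15 with the slow fibre score and 0 without number 3 arrays or with the RNA signal. Genotype over both ages gave 1 with array weights, and 1 with the block and the RNA signal.

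Lists called with an estimated correlation were 0 for genotype in young mice, 0 for age in control mice, 1 for genotype in old mice, 0 for age in KO mice, 0 for the interaction, 0 for genotype and 2 for age over all mice, and with the block as well 0 in each. Directional fry gave 0 in each and mixed fry 0 in each but age over all mice (1). With the block directional fry gave 1, 1, 2, 7, 0, 4 and 11 in the same order. Family as a fixed block gave 11 for genotype in old mice, 17 for age in KO mice and 13 for age over all mice, and with the block 11 for age in control mice, 15 for age in KO mice, 3 for the interaction and 13 for age over all mice. With the block 13 lists were called for genotype in young mice and 9 in old mice without number 3 arrays, and 11 in young mice with the slow fibre score. With the block and the RNA signal 16 were called for age in KO mice, 12 for the interaction and 14 for age over all mice. With family fixed, which rests age on few mice, lists for age turned sign: the median for age over all mice was -0.0818 for antigen presentation, -0.0320 for autophagy, -0.0594 for lysosome, -0.0873 for interferon response and -0.0474 for unfolded protein response genes, and with the block -0.0015 for antigen presentation, -0.0199 for lysosome genes, -0.0720 for complement and -0.0578 for macrophage markers, and -0.0494 for macrophage markers with age in control mice. Slow fibre genes for the interaction turned direction at 0.0669 with family fixed, -0.0994 with family and the block (where median and test differ in sign) and 0.0345 with the block and without number 3 arrays.

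The limma fit of Mfn2 gave an unadjusted p of 0.0254 for genotype in old mice, 0.0299 for genotype over both ages, 0.0792 for age in KO mice and 0.142 for age over all mice. For genotype in old mice Mfn2 lost this call at -0.40 for the mean of probe sets (0.105), -0.93 with family fixed (0.0767) and -0.63 with family and the block (0.101). Over both ages it lost the call at -0.32 for the mean of probe sets (0.0708) and -0.57 with family fixed (0.0908). For age in KO mice Mfn2 gained a call at -0.68 with quantile normalization (0.0438), and with the block at -0.71 (0.0123). With the block and a further choice it kept that call at -0.71 with the lowest 50% left out (0.0163), -0.51 with array weights (0.0260), -0.71 with scaled arrays (0.0120), -0.71 with the slow fibre score (0.0138) and -1.07 with the RNA signal (0.0137). For age over all mice it gained a call with the block at -0.41 (0.0328). With the block and a further choice it kept it at -0.41 with the lowest 50% left out (0.0406), -0.33 with array weights (0.0483), -0.40 with scaled arrays (0.0357), -0.43 with the slow fibre score (0.0318), -0.26 without number 3 arrays (0.0271) and -0.70 with the RNA signal (0.0295). For genotype in young mice it was -0.57 with the block and without number 3 arrays together (0.00237). For age in control mice it turned to 0.26 with family fixed (0.648). The correlation of the young KO with ageing was 0.0910 with family fixed.

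Leaving out 1 array in turn, with and without the block, genes ranged from 5 to 109 for age over all mice, 0 to 15 for age in control mice, 0 to 21 for age in KO mice, 0 to 1 for genotype in young mice, in old mice and the interaction, and 0 to 2 for genotype over all mice. With the block age over all mice stood at 62 without young KO replicate 2, and age in KO mice at 21 without old control replicate 1, 10 without old KO replicate 1 and 0 without young KO replicate 3. Lists ranged from 12 to 27 for genotype in young mice, 9 to 21 for genotype in old mice and for age in control mice, 22 to 31 for age in KO mice, 12 to 25 for the interaction, 14 to 26 for genotype over all mice and 20 to 29 for age over all mice. Of 49 list results 9 lost their call in at least 1 of these runs without the block and 4 with it, and the median moved by over 1.5 times in 35 and 27. Among them the median turned sign for mitophagy receptors with age over all mice (-0.0234 and -0.0061, without young control or young KO replicate 3) and in control mice (-0.0053, without young control replicate 3), and for the mitochondrial ribosome in the interaction (0.0092, without old KO replicate 3). It turned for antioxidant genes for genotype over all mice (-0.00033, without old control replicate 3). The median of slow fibre genes for the interaction ranged from -1.21 (without young control replicate 4) to 0.0746 (without young control replicate 3), both with the block. Mfn2 ranged from -0.60 to -0.13 for genotype in young mice, -0.37 to 0.10 for age in control mice, -1.16 to -0.46 for genotype in old mice, -0.94 to -0.24 for age in KO mice, -0.82 to -0.12 for the interaction, -0.77 to -0.40 for genotype and -0.54 to -0.18 for age over all mice. The correlation of the young KO with ageing ranged from 0.239 to 0.688, and that of the genotype differences at the 2 ages from -0.0481 to 0.286.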

Other observations

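Genes of 4 lists not yet described for this comparison, picked after their values were seen, ranked apart from other genes with age over both genotypes. Lysosome genes were higher in 21 of 30 members (median 0.07, camera adjusted p = 7.07e-06; adjusted p = 0.377 with an estimated correlation), among them the hexosaminidase subunit Hexa, which rose by 0.22 (SE 0.04) with the replicate block. Of lysosome genes 2 rose adjusted over the list alone, 3 with the block, and 0 over all genes, or 1 with the block. Interferon response genes were higher in 24 of 28 members (median 0.14, camera adjusted p = 6.24e-08; adjusted p = 0.317 with an estimated correlation). Unfolded protein response genes of the endoplasmic reticulum were higher in 24 of 27 members (median 0.07, camera adjusted p = 0.000349; adjusted p = 0.534 with an estimated correlation). Complex I genes were lower in 30 of 33 members (median -0.05, camera adjusted p = 1.29e-09; adjusted p = 0.372 with an estimated correlation). In the other 3 lists 0 genes passed adjusted over the list alone or over all genes in limma, and with the block 3 interferon response genes rose adjusted over the list alone. With family and the block in the fit, lysosome (median -0.0199, camera adjusted p = 0.580), interferon response (0.0067, 0.879) and unfolded protein response genes (0.0044, 0.994) lost their calls, and complex I genes did with the block and the 3 prime minus 5 prime signal of pyruvate carboxylase (-0.026, 0.237). Without old KO replicate 1 the interferon response median was 0.031. That of unfolded protein response genes was 0.031 without old control replicate 2 and 0.11 without old KO replicate 4. The antioxidant enzyme Gpx3 rose by 0.49 (SE 0.10) with the replicate block.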
